A study of Mus musculus with 24 samples.

How the data were processed

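RNA was sequenced from sorted cells of 12 mouse gliomas raised by transfer of PDGFB into the ventricles of the embryonic telencephalon. Per the labels' protocols, tumours were dissected under fluorescence, dissociated and sorted into fluorescent glioma cells and surrounding cells without fluorescence, which gave 24 libraries. Libraries were made from polyA RNA with a total RNA kit. The deposited values are expected counts per gene, estimated with RSEM 1.3.1 and STAR 2.7.5c on GRCm38, per the submitters' processing notes. The sources used here state neither the annotation release, the strand setting nor the use of molecular identifiers, so antisense and overlapping genes are uncertain. Genes with near-identical copies are uncertain too, since expected counts split their reads by estimate.

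The table held 55938 genes and 24 libraries, and from 13.2% to 16.5% of the values in a library were not whole numbers. Expected counts were rounded, which moved no library total by more than 95.2 counts. Totals ranged from 9.08e+06 to 1.55e+07 per library. No 2 libraries of a group were copies: the lowest chi-square per degree of freedom between such a pair was 19.8, well above the value that counting error alone gives. Where a symbol occurred more than once, the copy with the highest total was used for the gene lists. Of the identifiers, 98.7% were found in GENCODE release 21 of the mouse, from which coordinates were taken.

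Libraries were grouped by population and stage, 4 per group. The labels state whether an animal showed symptoms and the days after transduction. The symptomatic animals were divided into early and late by the letters that end their labels, a division that also separates the days. Tumours of a stage share code prefixes with no other stage, and stage, day and prefix cannot be told apart. Fits, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

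Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the tool's filter on low counts at a minimum of 10 and the robust quasi-likelihood test. Group means were the only terms. Stages were compared within the 12 libraries of a population. Glioma and surrounding cells were compared in all 24 libraries, as the mean of the 3 glioma groups minus the mean of the 3 surrounding groups. Differences of stage effects between the populations were tested as interactions in the same 24 libraries. P-values were adjusted by Benjamini and Hochberg over all genes tested, and adjusted p under 0.05 was called. The count of glioma against surrounding cells also required a fold of more than 2. Errors of log2 fold changes are standard errors derived from the F statistic. CPM are scaled by TMM over all 24 libraries.

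The 33 gene lists cover cell types that the sort could hold and pathways of glioma and immune cells: OPC, mature oligodendrocyte, astrocyte, neuron, neural progenitor and proneural, microglia, monocyte and macrophage, activated microglia, T and NK cell, B cell, neutrophil, dendritic cell, endothelial, pericyte and smooth muscle, fibroblast and meningeal, ependymal and choroid plexus, erythrocyte, mitosis, DNA replication, Myc target and nucleolar, interferon response, MHC class I, MHC class II, immune checkpoint and suppressive, hypoxia, glycolysis, oxidative phosphorylation, ribosomal protein, mesenchymal and matrix, PDGF and MAPK response, dissociation and immediate early, p53 pathway and cholesterol synthesis genes. Each list with at least 3 tested members was compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 219 tests of 7 comparisons. Camera with an estimated correlation and fry were run beside it. Called members were counted with the adjustment over all genes and adjusted over the list alone. Mean log2(CPM + 1) of each list was compared by exact permutation over the 70 assignments of 4 against 4 libraries. Glioma and surrounding cells were compared by exact sign flips over 12 pairs.

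Named genes follow a fixed rule. In each comparison they are up to 10 higher and 10 lower genes with the largest fold among those called, with a mean log2 CPM of at least 3 and no overlap between the groups, or with the same direction in all 12 pairs. To these were added up to 4 members of each list with the smallest p, and Pdgfb, Pdgfra, Olig2, Sox10, Myc, Mki67, Cdkn2a, Ptprc, Cx3cr1 and Gfap. Predicted genes, mitochondrial genes and receptor segments were left out.

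The alternatives were DESeq2 1.42.0, limma voom with sample weights, DESeq2 size factors, other count filters, no robust spread, other fold limits, all 24 libraries in 1 fit, single stages, marker covariates, exclusion of genes higher in the other population, each tumour left out in turn, and the tumour code as a block. Fits without tumours 3108D and 3109D, and a block with those codes exchanged, were added after the data were seen. The pairing comes from the labels, which give both libraries of a code to the same brain. For codes 3108D and 3109D the values contradict it. As a check, deviations from the group means were correlated between the libraries of a code. The correlation lay between 0.025 and 0.482 and was over 0.1 in 9 of the 12 pairs.

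The procedures were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each fold. For glioma against surrounding cells, edgeR recovered 11, 36, 50 and 50 genes at folds of 1.5, 2, 4 and 8, and called 6 unchanged genes. For late against early symptomatic glioma it recovered 1, 14, 41 and 49. For late against early symptomatic surrounding cells it recovered 1, 2, 28 and 47. In these 2 comparisons edgeR called 3 and 1 unchanged genes, limma voom with sample weights 2 and 1, and DESeq2 24 of 149 and 38 of 140 calls. No simulated library stood apart from its group, so sample weights were not tested where a library does. DESeq2 also recovered more changed genes, 27 and 11 at a fold of 2, and 44 and 41 at a fold of 4. A raised gene list was called in every comparison, and 0 of 99 unchanged lists were. The simulated genes were drawn independently, so this cannot show how the list test behaves when genes of a list vary together. Figures were drawn with matplotlib 3.10.9.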

Results

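Gene expression was measured in 24 libraries from 12 mouse gliomas driven by PDGFB, a growth factor whose receptor Pdgfra marks oligodendrocyte precursor cells (OPC). Per the labels each brain gave 1 library of fluorescent glioma cells and 1 of surrounding cells without fluorescence. The 4 asymptomatic tumours (3228A, 3228B, 3228D and 3229B) were taken at 33 to 34 days after transduction. The 4 early symptomatic tumours (3108C, 3108D, 3109D and 3145A) were taken at 35 to 50 days, and the 4 late symptomatic tumours (3054A, 3054B, 3054C and 3057E) at 100 to 175 days. Glioma cells of 3057E are labelled red and those of the other 11 tumours green. Totals of counts ranged from 9.08e+06 to 1.55e+07 per library. The first principal component held 55.8% of the variance, with the glioma libraries at -90.0 to -29.1 and the surrounding libraries at 23.3 to 161.

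Xist, transcribed from the inactive X chromosome, and Ddx3y, a gene of the Y chromosome, were read in each library as a check of the tumour codes. In the libraries coded 3108D, Xist stood at 1591 CPM in the glioma cells and at 2.08 CPM in the surrounding cells. In those coded 3109D it stood at 1.89 CPM in the glioma cells and at 1079 CPM in the surrounding cells, and Ddx3y went the opposite way. In the other 10 codes, both populations were on the same side for Xist. It was high in 3228A alone of the asymptomatic tumours, and in 3054A and 3054B of the late ones. Of the early symptomatic tumours it was high in 3108C and 3145A, and in glioma 3108D and surrounding 3109D. Sex was therefore not balanced over the stages, and it was not a term of the fits. Both tumours belong to the early symptomatic stage, so the groups compared do not depend on which code is right, but the pairs do.

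**Figure D1:**
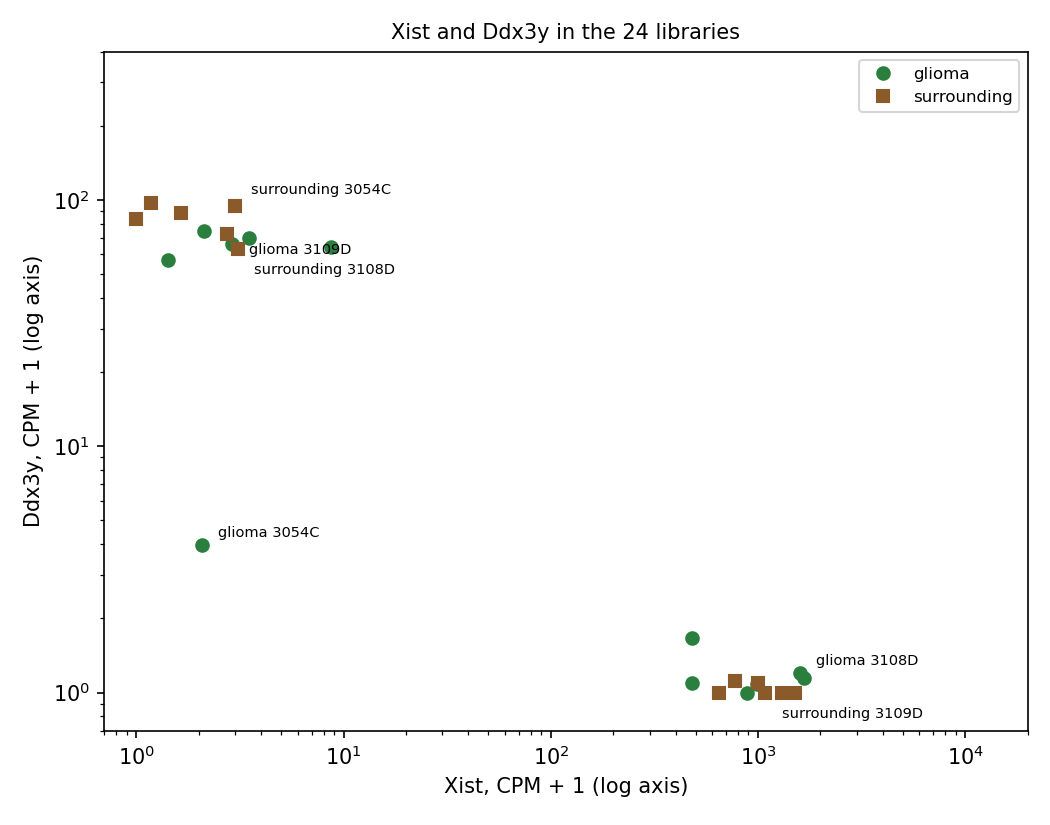
Xist against Ddx3y in CPM + 1 on log axes, with 1 point per library of glioma cells (circles) or surrounding cells (squares). Glioma 3108D and surrounding 3109D lie with the libraries high in Xist, glioma 3109D and surrounding 3108D with those high in Ddx3y, and glioma 3054C is low in both.

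Glioma and surrounding cells were compared to learn which transcripts separate the tumour cells from their neighbours. OPC markers were higher in the glioma cells, among them Pdgfra, a receptor of PDGF ligands (log2 fold change 1.09 ± 0.30, SE, n = 12 libraries per population). The surrounding cells also held these transcripts. Mean log2(CPM + 1) of OPC markers was 8.34, 8.36 and 6.99 in asymptomatic, early and late surrounding cells, against 9.05, 9.12 and 8.93 in glioma. Pdgfra stood at 136 to 3810 CPM in surrounding libraries and 2687 to 6036 CPM in glioma libraries, so the populations overlapped. The lineage factors Olig2 (1.07 ± 0.27) and Sox10 (0.97 ± 0.21) were higher in the glioma cells too. Microglia, vascular and other immune markers were lower, such as Tmem119 of microglia (-5.90 ± 0.53) and Pecam1 of endothelium (-4.49 ± 0.41). The proliferation gene Mki67 (1.03 ± 0.33) and the cell cycle inhibitor locus Cdkn2a (1.60 ± 0.28) were higher in the glioma cells. Pdgfb itself did not differ (0.30 ± 0.24, edgeR adjusted p = 0.33). The labels do not say whether the introduced copy is counted as the mouse gene.

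In this comparison edgeR called 4206 of 18810 genes at a fold of more than 2, 926 higher and 3280 lower in the glioma cells. Without the fold limit 8700 genes were called, 4144 higher and 4556 lower. The number of higher genes depended on single tumours and stages, with 606 without 3229B, 1450 without 3057E, and 105, 39 and 1732 in the asymptomatic, early and late symptomatic stages alone. A test against a 2-fold change called 58 higher and 2460 lower genes, and a stricter count filter, with 13870 genes tested, left 542 higher. The rule for named genes asks here for the same direction in all 12 pairs as coded. Among the genes that met it, the higher ones with the largest folds were Vit (3.06 ± 0.42), the protocadherin Pcdhb5 (2.24 ± 0.23) and the sialyltransferase St6gal2 (2.21 ± 0.50). The lower ones with the largest folds were Cd74 (-7.45 ± 0.73), the invariant chain of MHC class II, H2-Aa (-7.22 ± 0.69) and the collagen Col3a1 (-7.13 ± 0.83). Cd74 (ENSMUSG00000024610) lies on chromosome 18 at 60803848 to 60812652 in GRCm38.

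Of the 17 OPC markers 14 rose and 0 fell in glioma cells, and 14 did so adjusted over the list alone. Mitosis genes followed, with 25 of 26 higher (26 adjusted over the list alone), led by Ccnb1 (1.68 ± 0.26) and Cenpf (1.64 ± 0.28). DNA replication genes were higher in 14 of 26 (17 adjusted over the list alone), and cholesterol synthesis genes in 16 of 18 (17 adjusted over the list alone), with Sqle at 1.17 ± 0.27. These 4 lists passed the camera test, and adjusted p = 0.51 to 0.67 with an estimated correlation. Neural progenitor and proneural genes were higher in 12 of 18, with Sox11 at 1.55 ± 0.26 and Sox2 at 1.17 ± 0.19, and lower in 3, with Id1 at -2.40 ± 0.44 (13 and 4 adjusted over the list alone). Of 19 PDGF and MAPK response genes 12 were higher, such as the feedback inhibitor Spry2 (1.12 ± 0.22), and 4 lower, such as Pdgfrb (-5.99 ± 0.55), with the same numbers adjusted over the list alone. Both lists passed camera upwards, and adjusted p = 0.45 with an estimated correlation. Oxidative phosphorylation genes were higher in 5 of 27 (2 adjusted over the list alone), a list past camera with adjusted p = 0.75 with an estimated correlation.

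Lists of immune cells were lower in the glioma cells. All 14 microglia markers, 17 of 19 monocyte and macrophage markers (the other 2 rose), 21 of 22 activated microglia genes, 18 of 18 T and NK cell markers, 7 of 7 B cell markers, 9 of 9 neutrophil markers and 11 of 12 dendritic cell markers fell. The same numbers fell adjusted over the list alone, where 1 dendritic cell marker rose. MHC class II genes fell in 10 of 10, MHC class I genes in 19 of 19, interferon response genes in 28 of 30, and immune checkpoint and suppressive genes in 11 of 14 with 2 higher. These numbers too were the same adjusted over the list alone. Vascular and stromal lists fell as well: 13 of 14 endothelial, 9 of 11 pericyte and smooth muscle, 10 of 11 fibroblast and meningeal (11 adjusted over the list alone) and 20 of 24 mesenchymal and matrix genes (22). Of the mature oligodendrocyte markers 13 of 14 fell, among them Trf (-4.26 ± 0.33), and of the dissociation and immediate early genes 15 of 18, among them Btg2 (-3.84 ± 0.30), with the same numbers lower and 1 immediate early gene higher adjusted over the list alone. All of these lists passed camera downwards, and adjusted p = 0.34 with an estimated correlation. Ependymal and choroid plexus markers fell in 10 of 10 and erythrocyte genes in 5 of 6, both with the same numbers adjusted over the list alone. These 2 lists passed camera too, and adjusted p = 0.51 with an estimated correlation.

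The other 7 lists did not pass camera. Astrocyte markers were lower in 7 of 14, such as Gja1 (-3.87 ± 0.35), and 8 were lower and 1 higher adjusted over the list alone, with camera's adjusted p = 0.068. Hypoxia genes were lower in 10 of 22 and higher in 1, the same adjusted over the list alone, and camera gave an adjusted p = 0.052. Glycolysis genes went both ways with 2 higher and 2 lower of 19 (1 and 2 adjusted over the list alone). Ribosomal protein genes were lower in 2 of 32 (0 adjusted over the list alone), and Myc target and nucleolar genes higher in 7 and lower in 2 of 40, the same adjusted over the list alone. Of the 20 p53 pathway genes 7 were higher and 2 lower (7 and 3 adjusted over the list alone). Neuron markers had a median log2 fold change of -0.74 while camera gave them an upward direction (adjusted p = 0.78), with 2 of 14 higher, Syp (0.61 ± 0.18) and Gad1 (0.95 ± 0.33), and 1 adjusted over the list alone. The mean level of 28 of the 33 lists differed between the populations by exact sign flips over 12 pairs, whose smallest possible p is 0.000488. The 5 that did not were the neuron, Myc target, oxidative phosphorylation, ribosomal protein and p53 pathway lists. For stages, no exact test of 4 against 4 libraries can give p under 0.0286, and none passed after adjustment. Of the 219 list tests 126 passed camera, 26 of them for glioma against surrounding cells. The stage comparisons below name only a part of the others, so a list not named there may have passed too.

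**Figure D2:**
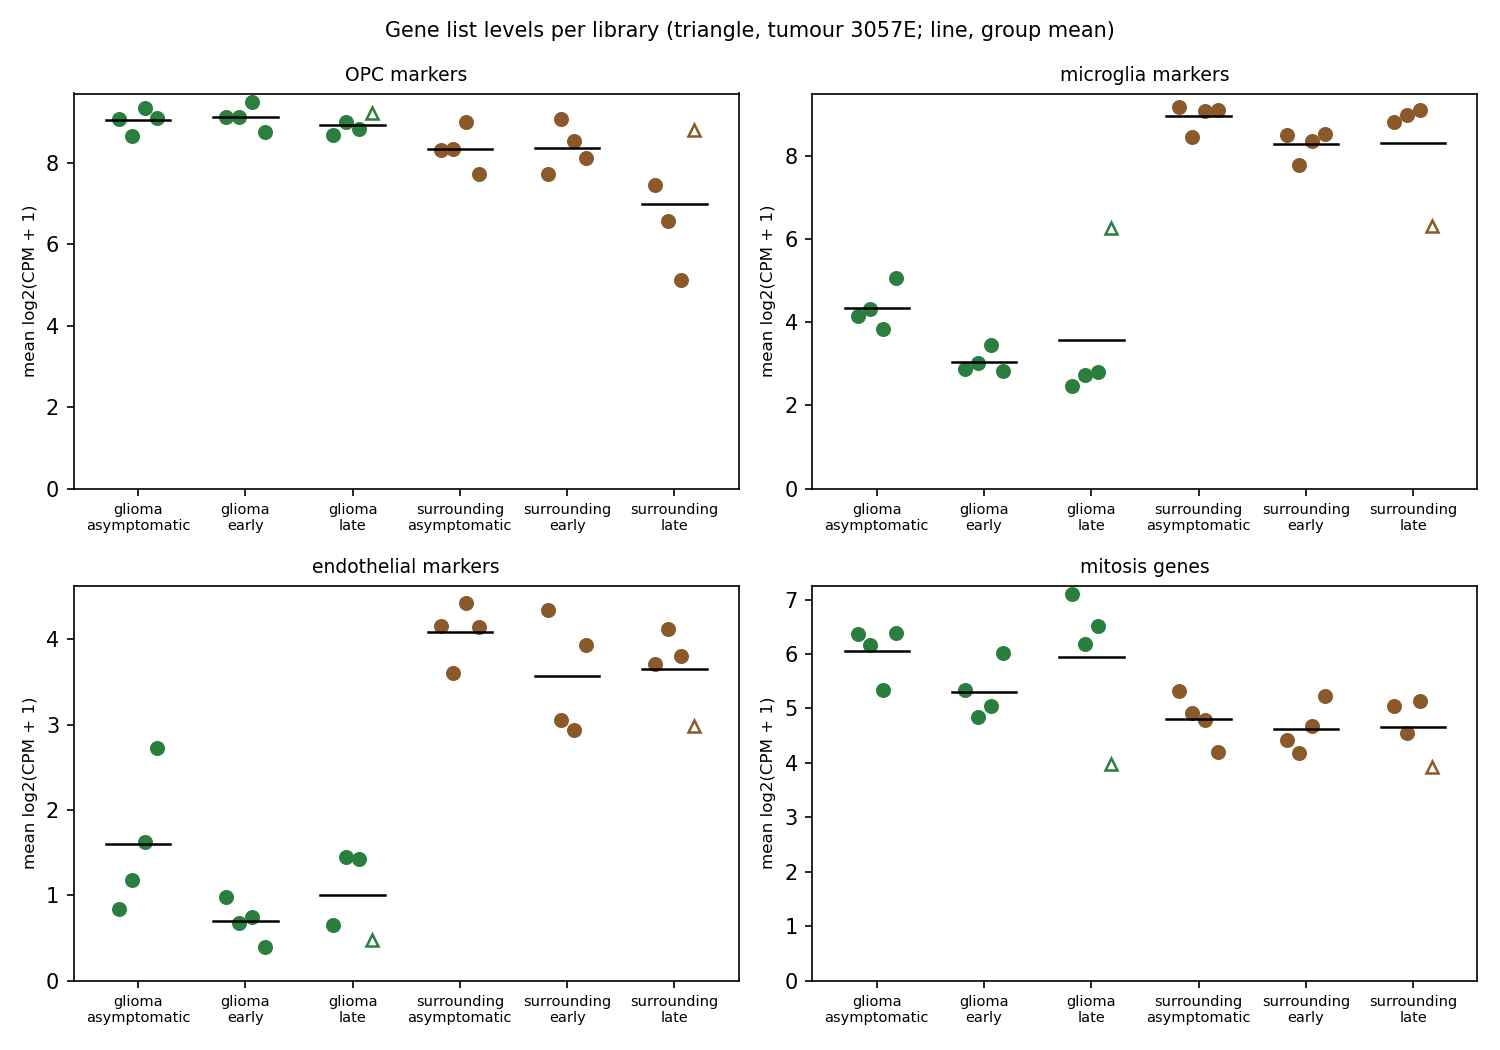
Mean log2(CPM + 1) of 4 gene lists in each of the 24 libraries by population and stage, with the group mean as a line and tumour 3057E as an open triangle. Glioma 3057E stands at 6.26 for the microglia markers, and the other late symptomatic glioma libraries at 2.47 to 2.80.

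Late and early symptomatic glioma cells were compared to see what separates long-lived from early tumours. In 3 of the 4 late tumours Cdkn2a stood far above the rest, at 83.5 CPM in 3054A, 132 CPM in 3054B and 141 CPM in 3054C, against 10.8 to 17.9 CPM in the early symptomatic glioma cells. The fourth late tumour, 3057E, stood at 17.4 CPM. Genes that rose past the test included Lox, a collagen crosslinking enzyme induced by hypoxia (3.49 ± 0.39, SE, n = 4 per group), Car9, a carbonic anhydrase of hypoxic cells (3.40 ± 0.64), and the receptor kinase Axl (2.41 ± 0.29). Genes that fell included the water channel Aqp4 (-1.87 ± 0.34), the amino acid transporter Slc1a4 (-1.53 ± 0.20) and Zmat3, a p53 target (-0.93 ± 0.17). Cdkn2a itself (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) had a log2 fold change of 2.80 ± 0.52 with edgeR adjusted p = 0.054.

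The test called 45 of 16494 genes, 33 higher and 12 lower. Among the higher were also Tmem123 (3.12 ± 0.38), Tnfaip3, a brake on NF-kB signalling (2.79 ± 0.51), Skap2 (2.50 ± 0.36), Tfpi (2.27 ± 0.34), Sema3e (2.27 ± 0.41), Rarb (2.23 ± 0.35), Nfe2l2 (2.01 ± 0.34) and Gpi1 (1.75 ± 0.30), a glycolysis gene whose reads can be shared with its pseudogene. Among the lower were Sfrp2 (-1.32 ± 0.24) and Kalrn (-1.26 ± 0.22). DESeq2 called 989 genes and limma voom with sample weights 2613. With all 24 libraries in 1 fit edgeR called 118 genes, 101 higher and 17 lower. With microglia markers as a covariate it called 1670, 789 higher and 881 lower. Among the late gliomas that covariate sets 3057E, at 6.26, apart from the others, at 2.47 to 2.80. The covariate fit is therefore not independent of the fit without 3057E. With genes higher in surrounding than in glioma cells left out, among them Lox and Axl, edgeR called 1 gene. Without 3057E edgeR called 2912 genes, 1453 higher and 1459 lower, among them all 45. The late tumours left, 3054A, 3054B and 3054C, share a code prefix that no other tumour has. Prefix and stage cannot be told apart there, and the 45 are no independent check, since the same libraries gave them. The same limit holds for every late comparison without 3057E. By contrast edgeR called 2 genes without 3108C, 4 without 3054B, 5 without 3054C or 3108D, 6 without 3145A and 7 without 3054A. It called 8 without 3109D, 9 without 3228A, 17 without 3229B and 23 without 3228B or 3228D. Lox and Axl were called in all 12 fits that left 1 tumour out. Over all alternatives the adjusted p ranged from 7.16e-13 to 0.115 for Lox and from 6.93e-12 to 0.115 for Axl.

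Hypoxia genes were higher in late than in early symptomatic glioma in 3 of 21 (16 adjusted over the list alone), with a median log2 fold change of 1.55, and glycolysis genes in 1 of 19 (13), with a median of 0.91. Both lists passed camera, and adjusted p = 0.34 with an estimated correlation. Without 3057E 18 of 22 hypoxia and 13 of 19 glycolysis genes rose. Interferon response genes had a median of 1.23, with 0 of 23 called and 13 adjusted over the list alone, and adjusted p = 0.45 with an estimated correlation. Here 3057E, the library high in microglia markers, stood highest at 4.03, against 2.49 to 3.18 in the other 3 and 2.07 to 2.59 in early symptomatic glioma. Mitosis genes (median 0.87), DNA replication genes (0.94) and ribosomal protein genes (0.54) passed camera upwards with 0 members called, and adjusted p = 0.51 to 0.72 with an estimated correlation. Without 3057E, 15 of 26 mitosis genes, 6 of 26 replication genes and 29 of 32 ribosomal protein genes rose. Mki67 had a log2 fold change of 1.47 ± 0.61, and stood at 85.9 CPM in 3057E against 665 to 1762 CPM in the other late gliomas.

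Among the p53 pathway genes 1 of 19 fell (10 fell and 2 rose adjusted over the list alone), with a median of -0.72 and camera past its threshold, and adjusted p = 0.39 with an estimated correlation. Without 3057E 10 of 19 fell, among them Zmat3, Eda2r and the cell cycle inhibitor Cdkn1a, and 2 rose, Cdkn2a among them. Cholesterol synthesis genes had a median of -0.62, astrocyte markers -1.52 with 1 of 14 lower, and neuron markers -1.21. These 3 lists passed camera downwards, and adjusted p = 0.49 to 0.65 with an estimated correlation. Microglia markers had a median of 2.25 and were not called (camera adjusted p = 0.26). In the glioma library 3057E, Ptprc of leukocytes stood at 69.4 CPM and Cx3cr1 of microglia at 275 CPM, against 0.42 to 1.67 and 3.04 to 6.67 CPM in the other 3 late gliomas. Of OPC markers 0 of 17 changed, and Pdgfra had -0.63 ± 0.19 with edgeR adjusted p = 0.13.

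**Figure D3:**
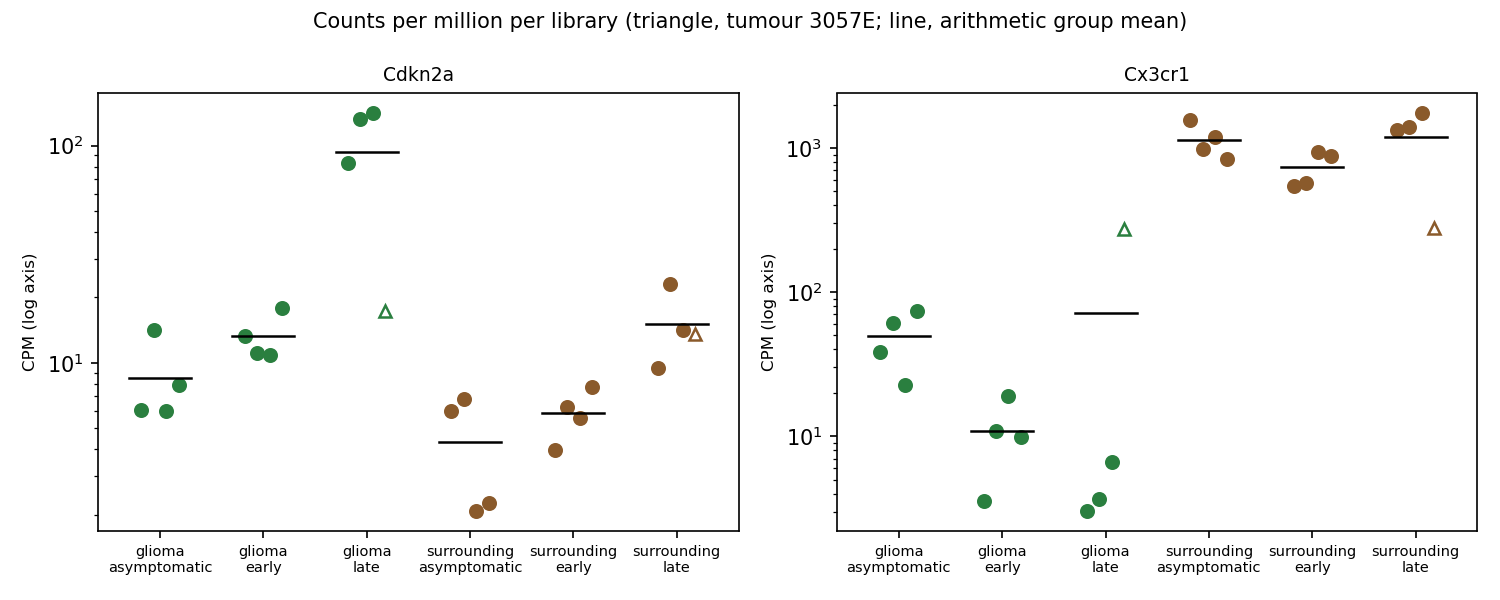
CPM of Cdkn2a and Cx3cr1 on log axes in each of the 24 libraries by population and stage, with the arithmetic group mean as a line and tumour 3057E as an open triangle. Cdkn2a stands at 83.5 to 141 CPM in 3 late glioma libraries and at 17.4 CPM in 3057E, and Cx3cr1 at 275 CPM in glioma 3057E.

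Early symptomatic and asymptomatic glioma cells, close in age but unequal in sex, were compared to see what goes with the onset of symptoms. No single gene passed the edgeR test at 16494 genes, with a smallest adjusted p of 0.936 and 810 genes at an unadjusted p under 0.05. DESeq2 called 0 genes and limma voom 1. Mki67 (-1.05 ± 0.61, SE, n = 4 per group), Cdkn2a (0.65 ± 0.50) and Pdgfra (0.21 ± 0.19) were not called. As lists, mitosis genes (median -0.78) and DNA replication genes (-0.68) passed camera downwards with 0 of 26 members called in each. Adjusted p = 0.57 and 0.45 with an estimated correlation. Microglia markers (-1.83) and erythrocyte genes (-3.08) passed downwards with 0 members called, and adjusted p = 0.44 and 0.34 with an estimated correlation. PDGF and MAPK response genes (0.19), cholesterol synthesis genes (0.41) and p53 pathway genes (0.22) passed upwards with 0 members called, and adjusted p = 0.34, 0.67 and 0.51 with an estimated correlation. Leaving out 3145A turned the direction of the cholesterol list, with a median of -0.07.

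Late symptomatic and asymptomatic glioma cells were compared across the widest span of days. Cdkn2a rose (3.45 ± 0.54, SE, n = 4 per group, edgeR adjusted p = 0.032), from 5.97 to 14.2 CPM in asymptomatic glioma. The retinoic acid receptor Rarb, Axl (2.35 ± 0.29), the interferon-induced Ifit1 (2.11 ± 0.34) and Lox (2.28 ± 0.36) rose as well. The astrocyte genes Slc4a4 (-3.26 ± 0.56), Aqp4 (-2.53 ± 0.34), Mlc1 (-3.22 ± 0.51) and Gja1 (-3.93 ± 0.69) fell, 4 of 14 astrocyte markers in all (6 adjusted over the list alone, with 1 higher). The astrocyte list passed camera, and adjusted p = 0.34 with an estimated correlation. Gpi1 (1.96 ± 0.31) and its pseudogene Gpi-ps (1.92 ± 0.33) were called together, and their reads cannot be assigned with certainty.

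This comparison called 26 genes, 18 higher and 8 lower. DESeq2 called 578, limma voom 2989, and edgeR without 3057E 2487, among them all 26. With genes higher in surrounding than in glioma cells left out edgeR called 7. Leaving out 3054C, 3228A, 3228D or 3229B left 0 calls, 3054B or 3109D 4, 3054A 8, 3108D 10 and 3108C 14, and no gene was called in all 12 fits that left 1 tumour out. The adjusted p of Cdkn2a ranged from 1.74e-09 to 0.140 over the alternatives. Hypoxia genes (median 1.35, 1 of 21 called, 16 adjusted over the list alone), glycolysis genes (1.16, 1 of 19 and 13) and interferon response genes (1.33, 1 of 23 and 18) passed camera upwards, and adjusted p = 0.34 with an estimated correlation. Ribosomal protein genes (0.72, 12 of 32 adjusted over the list alone) and oxidative phosphorylation genes (0.45, 9 of 27) passed with 0 called over all genes, and adjusted p = 0.51 and 0.43 with an estimated correlation. Microglia markers had a median of 0.47 while camera gave a downward direction, with adjusted p = 0.67 with an estimated correlation. Without 3057E their median was -3.30 and 9 of 13 fell, and Cx3cr1 (-3.47) and Ptprc (-3.14) fell, which both had a positive log2 fold change with it (0.60 and 1.21 ± 1.23, not called).

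Surrounding cells of late and early symptomatic tumours were compared to see how the neighbourhood of the tumour differs. Some genes of antigen presentation and of leukocytes were called higher in the late surroundings, though none was called without 3108D, 3109D or 3145A. They included the MHC class II chains H2-Aa (3.80 ± 0.62, SE, n = 4 per group) and H2-Ab1 (3.79 ± 0.64), Plac8 of monocytes (4.63 ± 0.62), Itgae, an integrin of resident T cells and dendritic cells (4.19 ± 0.69), the chemokine receptor Ccr7 (4.59 ± 0.71) and the T cell receptor component Cd3g (4.27 ± 0.77). The interferon-induced Ifi205 (4.50 ± 0.67) and Mndal (3.88 ± 0.55) rose too. Among the 12 genes that fell were the monoamine transporter Slc29a4 (-1.84 ± 0.28), Slc1a4 (-1.79 ± 0.37), the pericyte gene Rgs5 (-1.64 ± 0.35) and Rasl11a (-2.12 ± 0.43).

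The test called 260 of 17616 genes, 248 higher and 12 lower. MHC class II genes rose in 8 of 10 (10 adjusted over the list alone), MHC class I genes in 3 of 19 (19), interferon response genes in 12 of 30 (28), monocyte and macrophage markers in 7 of 19 (13), T and NK cell markers in 4 of 18 (16) and dendritic cell markers in 4 of 12 (10, with 1 lower). Neutrophil markers rose in 1 of 9 (9), and erythrocyte genes in 0 of 5 (5), with log2 fold changes of the globins that their near-identical copies make uncertain. All 8 lists passed camera upwards, and adjusted p = 0.34 with an estimated correlation. Their median log2 fold changes ran from 1.24 for MHC class I to 4.75 for erythrocyte genes. Mean log2(CPM + 1) of erythrocyte genes was 4.04, 1.73 and 4.24 in asymptomatic, early and late surrounding cells. Late cells thus stood near the asymptomatic ones. T and NK cell markers stood at 1.29, 0.50 and 1.80, and their late and asymptomatic libraries overlapped. Those of the dendritic cell, MHC class I, and monocyte and macrophage lists overlapped too. For MHC class II, interferon response and neutrophil lists every late library lay above every asymptomatic one. Hypoxia genes had a median of 1.07 with 1 of 22 called, Egln3 (3.25 ± 0.72), and 7 adjusted over the list alone. That list passed camera, and adjusted p = 0.53 with an estimated correlation. OPC markers had a median of -0.91 and cholesterol synthesis genes of -1.03, both past camera with 0 members called, and adjusted p = 0.51 with an estimated correlation. Astrocyte markers (median -1.32), neuron markers (-1.96) and neural progenitor genes (-0.88) passed camera downwards too with 0 members called, and adjusted p = 0.45, 0.60 and 0.34 with an estimated correlation. Pdgfra stood at 136 to 814 CPM in the surrounding cells of 3054A, 3054B and 3054C, against 1926 to 3288 CPM in the early ones and 2751 CPM in 3057E.

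DESeq2 called 1149 genes and limma voom 5193. Without 3057E edgeR called 3406 genes, 1656 higher and 1750 lower, among them all 260, and MHC class II rose in 10 of 10, interferon response in 24 of 30 and hypoxia in 11 of 22, while OPC markers fell in 10 of 17. Leaving out 3108D, 3109D or 3145A left 0 calls. With OPC markers as a covariate 27 genes were called. Leaving out 3054B left 63 calls, 3054C 88 and 3054A 151. The adjusted p ranged from 7.48e-09 to 0.365 for H2-Aa and from 7.14e-13 to 0.354 for Plac8 over the alternatives. In the surrounding cells of 3057E the microglia markers stood at 6.32 on the log2 scale, against 8.82 to 9.12 in the other 3 late libraries. Leaving it out gave the microglia list a median of 0.74 with an upward camera call, where with it the median was 0.39 and camera pointed down without a call.

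**Figure D4:**
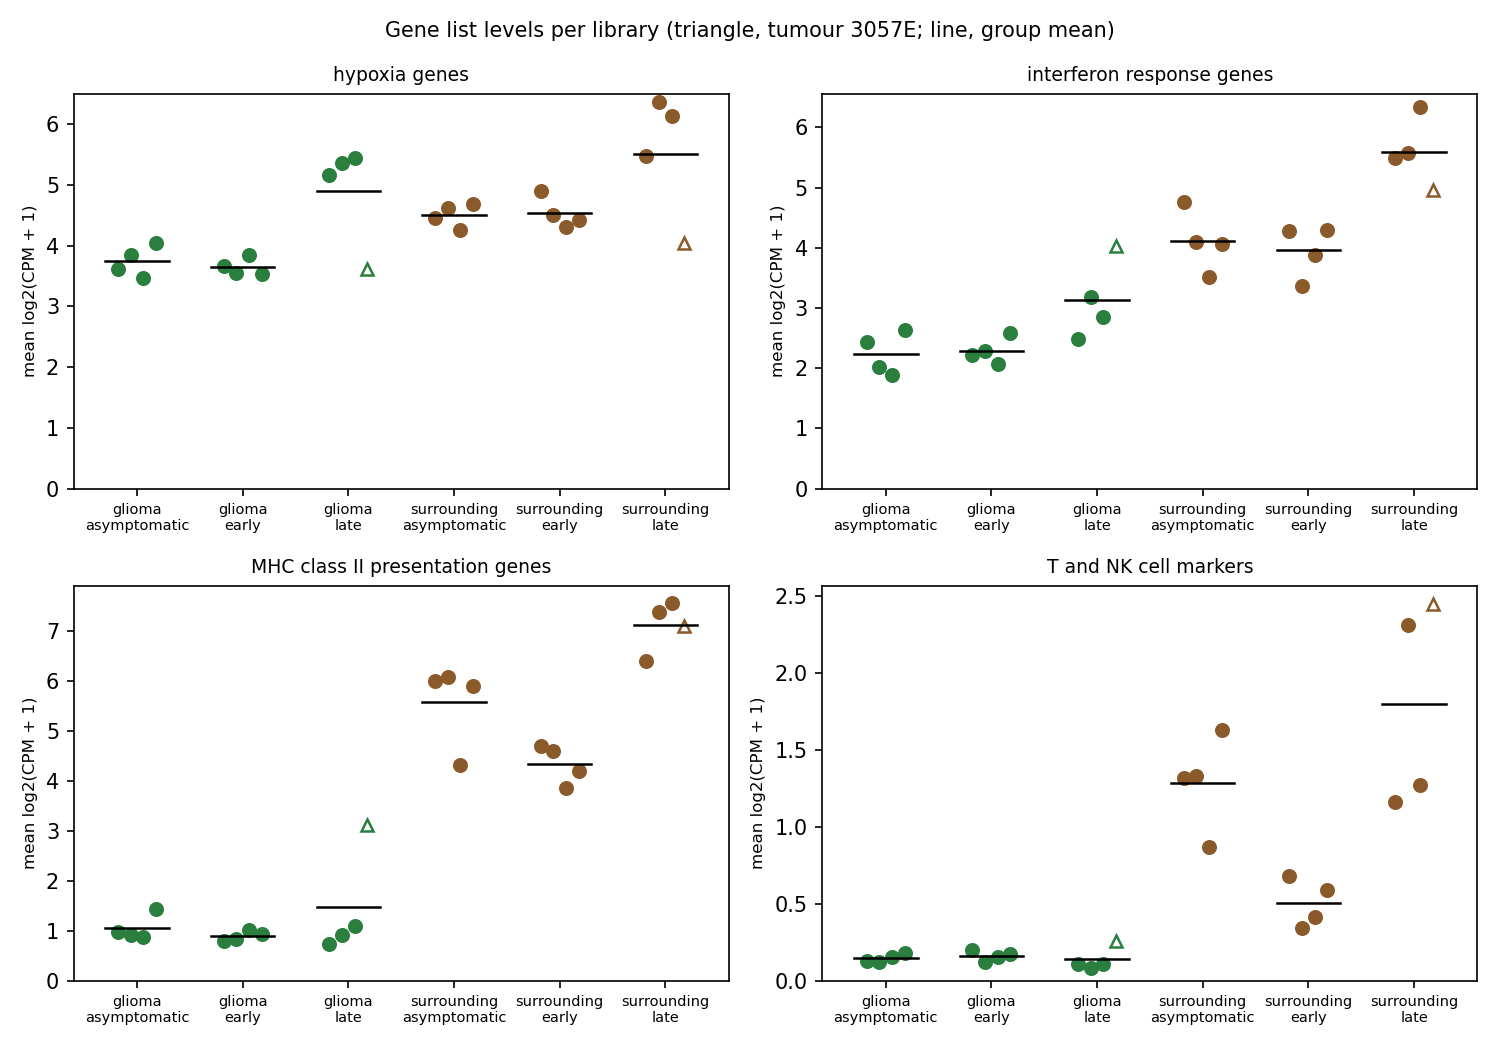
Mean log2(CPM + 1) of 4 gene lists in each of the 24 libraries by population and stage, with the group mean as a line and tumour 3057E as an open triangle. Hypoxia genes of glioma 3057E stand at 3.61, within the 3.47 to 4.05 of asymptomatic glioma, and MHC class II genes of late surrounding cells at 6.39 to 7.57.

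For early symptomatic against asymptomatic surrounding cells edgeR called 0 genes, with 645 at an unadjusted p under 0.05, while DESeq2 called 10 and limma voom 0. T and NK cell markers had a median log2 fold change of -2.28, MHC class II genes of -1.76, dendritic cell markers of -1.36 and erythrocyte genes of -4.03. These 4 lists passed camera downwards with 0 members called and 13 of 18, 9 of 10, 1 of 12 and 5 of 5 lower adjusted over the list alone. Adjusted p = 0.34 with an estimated correlation for each. Microglia markers (median -0.63) and endothelial markers (-0.41) passed downwards with 0 members called, and adjusted p = 0.57 and 0.48 with an estimated correlation. Without 3108D and 3109D the endothelial list had a median of -0.0636, the direction of camera turned and the call was lost, as it was without 3109D alone (-0.28).

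For late symptomatic against asymptomatic surrounding cells edgeR called 0 genes, with 2822 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0827, that of Rgs5 (-2.41 ± 0.36, SE, n = 4 per group). DESeq2 called 1002 genes, limma voom 4106, edgeR without 3057E 2962, and edgeR with all 24 libraries in 1 fit 226, 120 higher and 106 lower. Interferon response genes had a median of 1.56 with 28 of 30 higher adjusted over the list alone, and MHC class I genes 1.14 with 16 of 19. Mesenchymal and matrix genes had 1.67 with 11 of 24, monocyte and macrophage markers 2.03 with 12 of 19, and astrocyte markers -1.67 with 10 of 14 lower. These 5 lists passed camera, and adjusted p = 0.34 with an estimated correlation. Neuron markers had a median of -3.70 with 11 of 13 lower adjusted over the list alone, and adjusted p = 0.51 with an estimated correlation. Surrounding 3229B, of the asymptomatic group, stood at 6.23 for the neuron markers against 3.10 to 3.55 in the other 3, and held 30.3% of its counts in mitochondrial genes against 10.9% to 13.4%.

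Whether a stage effect differed between glioma and surrounding cells was tested as an interaction over 18810 genes, and edgeR called 0 genes in each of the 3 tests. At an unadjusted p under 0.05 stood 1167 genes for late against early, 290 for early against asymptomatic and 1585 for late against asymptomatic. DESeq2 called 43, 1 and 18 genes, and limma voom 1113, 0 and 1286. Cdkn2a had an interaction of 1.46 ± 0.68 for late against early (edgeR adjusted p = 0.795) and Lox one of 3.41 ± 0.79 (0.390), so a stage effect of either gene is not shown to be particular to the glioma cells. Without 3057E the counts were 869 for late against early and 1435 for late against asymptomatic. The tumour code as a block left 0 calls in each of the 3 tests.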

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

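All tests of the 3 patterns weighed here were chosen after their results were seen, while the counts over other splits of the samples were planned. In 270 groups of 4 libraries the gap between the highest or lowest library and its nearest neighbour was compared with Dixon's 95% limit, and 26 groups passed it, where chance gives about 1 in 20, or 13.5. Of the 26, 10 concern tumour 3057E, 8 of them its glioma library.

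The glioma library 3057E stood apart from the other 3 late glioma libraries in list levels, given as mean log2(CPM + 1). Microglia markers stood at 6.26, activated microglia genes at 7.01, monocyte and macrophage markers at 3.29, B cell markers at 0.939 and MHC class II genes at 3.12, all above the others. Its hypoxia genes stood at 3.61, below them, and its Ptprc at 6.14 and Cx3cr1 at 8.11 above them on the log2 scale. The surrounding library 3057E had its microglia markers at 6.32 and Cx3cr1 at 8.12, both below the other 3.

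Among asymptomatic glioma libraries, 3229B stood high for B cell markers (0.624) and for pericyte and smooth muscle markers (1.56), 3228D low for ribosomal protein genes (7.68) and 3228B low for Olig2 (8.81). Among early symptomatic glioma libraries, 3145A stood low for astrocyte markers (3.80) and 3108C high for neutrophil markers (0.396). Of the late ones, 3054A stood low for ependymal and choroid plexus markers (0.215) and 3054C low for Pdgfra (11.4). Among asymptomatic surrounding libraries, 3229B stood high for the share of counts in mitochondrial genes (30.3%), for neuron markers (6.23) and for oxidative phosphorylation genes (7.11). In the same group 3228B stood low for microglia markers (8.47) and 3228D low for activated microglia genes (6.82) and MHC class II genes (4.31). Among early symptomatic surrounding libraries, 3108D stood low for Pdgfb (4.48) and 3108C low for Olig2 (7.42). No explanation of the values in this paragraph was tested.

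The first pattern is that the glioma and surrounding libraries coded 3108D, and those coded 3109D, carried opposite Xist and Ddx3y. Loss of the Y chromosome is argued against by Xist at 1591 CPM in glioma 3108D, and cells of another animal mixed in by the lesser of Xist and Ddx3y, at most 2.08 CPM in the 4 libraries. With the codes exchanged in 1 population, 67.3% of 1512 autosomal genes that mark a tumour came closer, against 20.5% to 42.8% for the other 17 pairs of tumours in a stage. An exchange of the 2 codes in either the glioma or the surrounding libraries is a candidate explanation, and which population it concerns stays open.

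The second pattern is the distance of glioma 3057E from 3054A, 3054B and 3054C. Its microglia markers were at 16.3% of the level in the other surrounding libraries and at 102% of that in its own, so the share of microglia is not settled by these markers. Hypoxia genes differed by a median of -1.58 (interquartile range -2.44 to -1.06, 20 of 21 lower), while OPC markers, which microglia would dilute alike, stood at 9.21, the highest of the 4 late gliomas, whose lowest was 8.68, which argues against microglia as the whole cause. Its hypoxia level of 3.61 lay below both its own surrounding library, at 4.04, and the other late gliomas, at 5.17 to 5.45, which a mixture of such cells would not give. Of the other 3 late glioma libraries 0 share the code prefix or the fluorescent marker of 3057E, so animal batch, day and marker cannot be told apart from the tumour, a biological difference between late tumours stays open and untested, and microglia stay open for the microglia markers.

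The third pattern is a low level of Y chromosome transcripts in glioma 3054C, with Ddx3y at 2.96 CPM against 93.2 CPM in its surrounding cells. Over 4 Y genes the log2 difference ran from -4.57 to -3.25, while the lowest in the other 4 male pairs was -2.05. A first form of this test included Gm47283, gave -0.49 and went against the prediction; the gene was left out after its value was seen, since it stood at 62.6 CPM in libraries with Xist. Female cells are argued against by Xist at 1.06 CPM, and an exchange with 3054A or 3054B by at most 36.3% of genes coming closer. Loss of the Y chromosome in these glioma cells is a candidate explanation, found and tested on the same data.

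Other splits of the libraries were counted for every gene count, the real split included. For glioma against surrounding cells 1 of 100 splits called as many genes as the real 4206, and the highest other called 3205, which excludes chance. For late against early symptomatic glioma 3 of 35 splits called at least the real 45, the highest other 1686, with 3145A in place of 3057E. For late symptomatic against asymptomatic glioma it was 2 of 35 with the real count at 26 and the highest other at 1487, with 3228B in place of 3057E. For late against early symptomatic surrounding cells it was 2 of 35 with the real count at 260 and the highest other at 4118, with 3108C in place of 3057E. For these 3 counts the splits did not argue against chance. Splits that call several times the real count point to a structure of the samples, and each of these 3 joins 3054A, 3054B and 3054C with 1 other tumour. Those 3 lay closer to each other than to 3057E. Chi-square per degree of freedom was 32.4 to 42.5 among their glioma libraries, and 102 to 107 between these and glioma 3057E. In surrounding libraries it was 44.5 to 85.3 and 115 to 297. The remaining splits that join those 3 with another tumour called 202, 10 and 1 genes in the first comparison. In the second they called 1, 0 and 1, and in the third 0. Thus 3057E stood apart within the late group, while why only some of these splits call many genes stays open. With a real count of 0 all 35 of 35 splits call as many by construction, which says nothing about chance. The highest other count was 0 for early symptomatic against asymptomatic glioma, 1 for the same stages of surrounding cells and 0 for late symptomatic against asymptomatic surrounding cells. For the interactions it was 1426 for late against early, 0 for early against asymptomatic and 642 for late against asymptomatic.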

How the results depend on the processing

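Fits without tumours 3108D and 3109D and the block with their codes exchanged were chosen after the data were seen, and the other alternatives before. The count of glioma against surrounding cells kept within 1.5 times of 4206 under DESeq2, limma voom, other size factors, the late stage alone, the replicate block (4603), the exchanged block (4633) and each tumour left out (3942 to 5139). It was 2777 with a stricter count filter, 2518 in a test against a 2-fold change and 8700 with no fold limit, where the criterion itself changes, and 2273, 2255 and 4967 in the asymptomatic, early and late symptomatic stages alone. Its 926 higher genes moved further, to 606 without 3229B, 1450 without 3057E, 542 with a stricter count filter and 1442 with limma voom. The test against a 2-fold change gave 58 higher genes, and the single stages 105, 39 and 1732. Stage counts depended on the tool and the tumours, and the cause was not tested unless named. They follow in the order late against early, early against asymptomatic and late against asymptomatic. DESeq2 gave 989, 0 and 578 genes in glioma, 1149, 10 and 1002 in surrounding cells, and 43, 1 and 18 interactions. Limma voom with sample weights gave 2613, 1 and 2989, then 5193, 0 and 4106, then 1113, 0 and 1286. All 24 libraries in 1 fit gave 118 and 47 genes for the late stage against the early and the asymptomatic one in glioma, and 433 and 226 in surrounding cells. With marker covariates these were 1670 and 46 in glioma, and 27 for late against early surrounding cells. No filter gave 145 and 110 in glioma and 4 for late against asymptomatic surrounding cells. Without genes higher in the other population 1 and 7 remained in glioma. Without 3108D and 3109D glioma gave 4, 1 and 0 and late against early surrounding cells 0. The exchanged block gave 2 interactions for late against early, and the replicate block 0.

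With 1 tumour left out, glioma gave 2 (without 3108C) to 2912 (without 3057E) genes for late against early and 0 (without 3054C, 3228A, 3228D or 3229B) to 2487 (without 3057E) for late against asymptomatic. Surrounding cells gave 0 (without 3108D, 3109D or 3145A) to 3406 and 0 to 2962, and the interactions 0 to 869 and 0 to 1435, each highest without 3057E. Of 219 list tests 126 passed camera, 0 with an estimated correlation and 41 with fry.

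Some directions reversed, and the cause was not tested. For late symptomatic against asymptomatic glioma, limma voom gave -3.00 for Ighm, -2.79 for Csf3r, -2.64 for Ptprc and -2.93 for Cx3cr1. With 1 tumour left out these ran from -3.17 to 0.46, -3.33 to 1.29, -3.14 to 1.60 and -3.47 to 0.98, and Itgax from -2.81 to 2.87. Siglech ran from -2.20 to 2.703 for late against early glioma. All 6 were lowest without 3057E. List medians ran from -0.0700 (without 3145A) to 0.62 for cholesterol synthesis in early symptomatic against asymptomatic glioma, and from -0.23 to 0.57 (without 3057E) for mitosis in late against asymptomatic glioma. In surrounding cells microglia markers ran from 0.10 to 0.74 for late against early and from -0.44 to 0.22 for late against asymptomatic, highest without 3057E. For early symptomatic against asymptomatic surrounding cells, oligodendrocyte markers ran from -0.82 to 0.53, oxidative phosphorylation from -0.29 to 0.20 and ribosomal protein genes from -0.25 to 0.27, highest without 3229B. Immediate early genes ran from -0.12 to 0.25 (without 3108D). Oxidative phosphorylation ran from -0.24 to 0.30 (without 3229B) for late against asymptomatic. Without 3108D and 3109D, endothelial markers had -0.54 for late against early and -0.0636 for early against asymptomatic surrounding cells, and interferon genes 0.12 for the latter. The direction of a list is that of camera, which can differ from the sign of its median. Depth was 9.08e+06 to 1.55e+07 counts per library, and genes under the filter were not tested.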

Other observations

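Without tumour 3057E, 10 of 19 p53 pathway genes fell in late against early symptomatic glioma cells. The receptor gene Eda2r had a log2 fold change of -3.65, Cdkn1a of -2.18 and Zmat3 of -1.12, while Cdkn2a had 3.13 and Mki67 1.84. These genes were picked after their values were seen, and no explanation was tested.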
